A study of Homo sapiens with 20 samples.

How the data were processed

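DNA methylation was measured by enzymatic methyl-sequencing (EM-seq), in which enzymes rather than bisulfite convert unmodified cytosines; methylated and hydroxymethylated cytosines are read alike, so a level is the sum of both. The labels list 20 libraries in 9 groups. The groups are 4 human induced pluripotent stem cell (iPSC) lines, hehd1, sojd3, burb1 and fiaj1, each untreated and after chromatin restoration treatment (CHR), and the embryonic stem cell line H9, untreated. Each group has 2 replicates from independent experiments, and 2 further libraries repeat replicate 1 of sojd3 with control DNA added. Per the labels' protocols, untreated cells grew in Essential 8 medium on vitronectin, and CHR cells grew in StemFlex with 3 µM IWP2, an inhibitor of Wnt secretion, on laminin-521 for at least 8 passages. Treatment is therefore also a change of medium and coating. It also comes with at least 8 passages, while no passage number is listed for untreated cells, so time in culture may differ as well. The labels give 2 sequencing batches, with 7 libraries in batch 1 and 13 in batch 2. Both columns of burb1 and of hehd1 come from batch 2, both H9 libraries from batch 1, and the fiaj1 and sojd3 columns from both. For sojd3 the numbers are unequal only when the libraries with control DNA are counted.

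The authors deposited 1 table of percent methylation for 565390 genomic windows of unequal length, with 1 column per group. The replicates, and the libraries with control DNA if they were used, had thus been combined before deposit. How they were combined, how the windows were drawn and which coverage filter was used are not given in the sources used here. Coordinates are on GRCh38, per the labels. FastQC, cutadapt 4.6, Bismark 0.24.2 and SAMtools 1.21 are named, without roles, per the submitters' processing notes. The table gives no read or cytosine counts, so the depth behind each value is unknown and no interval for a single value can be given. Counting error may differ between windows, and whether it depends on their length cannot be told from these values.

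Because replicates were combined, the replicate here is the cell line: 4 pairs of columns for CHR against untreated. The tests had been planned before the data were examined for single libraries, with counts if present. The percent values and pooled columns called for limma on levels with lines as units, and the planned tests within a line could not be made. The planned interaction of line and treatment was replaced by a comparison of the change in 1 line with the changes in the other 3 lines, each line in turn.

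Windows on chromosomes X and Y and the mitochondrial genome were left out of all tests. Of 539017 autosomal windows, 481370 (89.31%) had a value in all 9 columns and were kept. Missing values fell mostly in short windows: 12.1% of windows up to 0.5 kb were kept, against 98% of those of 8 to 16 kb, and 46.5% of those over 16 kb. The median length of the kept windows was 4853 bp.

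Fits used limma 3.58.1 in R 4.3.3 on levels in percentage points, with empirical Bayes moderation and a prior that follows the mean level. CHR was compared with untreated with the line as a block. H9 was compared with the 4 untreated columns and with the 4 CHR columns as 1 column against 4. A window passed when its Benjamini-Hochberg adjusted p was under 0.05 and its difference at least 10 percentage points. The comparison of 1 line with the other 3 was first run with a prior that followed the mean change, and no window passed in any line. The prior was then set to follow the mean level, as in the other fits, after that result had been seen. Mean levels were compared by exact permutation within lines, which cannot give a two-sided p under 0.125 with 4 lines.

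A position on the axis of change was computed for each line in turn. The 1000 windows with the smallest p in the fit without that line were taken. Each column of that line, and H9, was then projected onto the difference between the mean CHR and mean untreated levels of the other 3 lines, so that 0 is their untreated and 1 their CHR level. The 95% intervals come from leaving out each chromosome in turn and describe spread over the genome, not between replicates.

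Genes were taken from a RefSeq table with gene spans only. It holds no strand and no exon boundaries, so a window is described as inside a gene, across its low- or high-coordinate end, or outside it within 1.5 kb. For gene lists, each gene had 1 value: the mean over windows overlapping 1500 bp outside to 500 bp inside the gene end with the lower mean level over the 9 columns. This end need not be the promoter. Genes sharing the same windows were counted once, which left 17723 units from 18687 genes. The 16 lists, fixed before the data were examined, cover core, naive, and primed and formative pluripotency, anterior neural fate, primitive streak with mesoderm and endoderm, neural crest and later neural markers, the Wnt pathway, TGF-beta, BMP and FGF signalling, HOX genes, imprinted genes, germline genes, loci variably methylated in human pluripotent lines, clustered protocadherins, regulators of DNA methylation and chromatin, trophoblast and amnion markers, and fibroblast and mesenchymal markers. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry.

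Windows named in the text followed a rule fixed beforehand. For CHR over 4 lines it took the 10 largest rises and 10 largest falls that passed and went the same way in every line, 1 per gene, filled up with the smallest p where fewer passed. For H9 it took the 5 largest differences each way outside the range of the lines, and for each list up to 3 members with the smallest p. For each line it took the 3 largest changes each way that passed a test within the line. That test could not be made, so the changes within a line were taken by size alone, a departure from the rule. POU5F1, NANOG, SOX2 and DNMT3B were given in any case. Windows with no gene within 1.5 kb were skipped, so a largest rise, fall or change named below is the largest among windows with a gene. Windows named for the fit without hehd1, for 1 line against the other 3 and in the TBX1 region were chosen after the data had been seen. A few items that the rule takes are not reported here.

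The fits were tested on simulated data with 50 windows at each size of change among 481370, under both of 2 noise models. With noise drawn from each window's own residual spread, run first except for 1 line against 3, 0, 0, 0 and 18 of 50 changes of 10, 20, 30 and 50 points were recovered with 4 lines, and none of any size with 3 lines, for H9 or for 1 line against 3; no unchanged window passed. After that result, noise from the moderated spread was tried. It gave 8, 39, 50 and 50 of 50 with 4 lines, 4, 29, 46 and 50 with 3 lines, 0, 19, 42 and 49 for H9, and 0, 5, 28 and 46 for 1 line against 3. In those runs 19, 19, 5 and 12 unchanged windows passed as well, more than 5% of the calls in some of them. Median estimates lay close to the simulated sizes in both models. Small counts of passing windows can therefore hold false calls, and windows that did not pass can hold large changes.

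Alternatives were logit levels with an offset of 1 percentage point, centring of each column on its median, a minimum difference of 20 points, each line left out in turn, chromosomes 8, 19 and 20 left out in turn, a prior without a trend, no line block, windows of at least 1 kb, and windows with values in at least 3 lines. Coverage filters, coverage weights, batch terms, exclusion of single libraries or replicates, and promoters defined by strand could not be tried on this table. Figures were drawn with matplotlib 3.10.9.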

Results

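The series measured DNA methylation in human pluripotent stem cells that differ in whether they can form unguided cerebral organoids, before and after a culture treatment named chromatin restoration (CHR). The lines hehd1, sojd3, burb1 and fiaj1 are induced pluripotent stem cells with an untreated and a CHR group each, and H9 is an embryonic stem cell line described as naturally competent. Which of the 4 other lines is competent is not given in the labels. Each of the 9 groups has 2 replicates, which the table holds as 1 combined column, so values of a single column have no replicate error and the spread given is that between lines. Depth is unknown. Values are methylation levels in percent over 481370 autosomal windows.

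The first comparison asked whether CHR changed the mean methylation level. Windows averaged 85.9% ± 0.432 in the untreated columns and 87.3% ± 0.234 after CHR (SD, n = 4 lines), with H9 at 86.9%. The level was higher after CHR in each line, by 1.94 points in fiaj1, 1.51 in burb1, 1.14 in sojd3 and 0.927 in hehd1, and on each of the 22 autosomes in each line. The mean difference of 1.38 ± 0.443 points (SD, n = 4) gave p = 0.125 in a two-sided exact permutation test within lines, which is the smallest p the design allows. The columns of burb1 and hehd1 were sequenced within 1 batch, so their differences of 1.51 and 0.927 are within-batch values. The fiaj1 columns have 1 library of each batch. In sojd3 there are 2 libraries of batch 1 and 1 of batch 2 untreated, and 1 and 2 after CHR. The imbalance comes from the libraries with control DNA, so treatment is partly confounded with batch if these were used. Without them each sojd3 column has 1 library of each batch.

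The higher level lay in methylated sequence. Windows averaging 80 to 90% were higher by 1.53 ± 0.617 points and those over 90% by 1.53 ± 0.386 points, in 4 of 4 lines each. Windows of 5 to 20% differed by -0.748 ± 1.16 points, with 1 of 4 lines higher, and those of 20 to 40% by -0.715 ± 1.27 points. Short windows of up to 0.5 kb, which averaged 17.1% in untreated cells, were lower in every line, by -0.212 ± 0.134 points. All of these have a smallest possible exact permutation p of 0.125. Windows with the same direction in all 4 lines made up 19.1% of the total, 16.5% higher throughout and 2.58% lower. Independent lines with the observed shares of rises and falls in each would give 17.1%. With each column centred on its median the share was 14.3%, against 12.7% expected in the same way, with 5.83% higher and 8.48% lower; these differences were not tested.

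**Figure D1:**
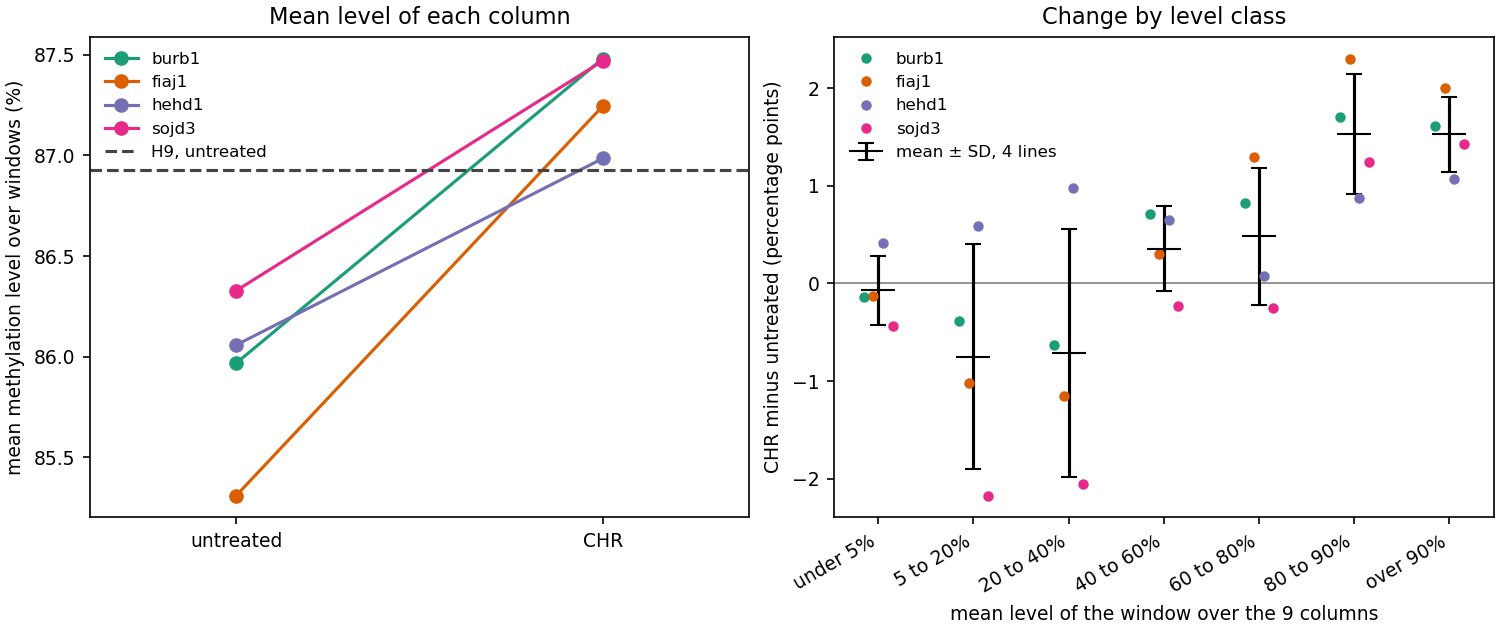
Left, mean methylation level in percent of each column, untreated and after CHR, joined by line, with H9 as a dashed line; all 4 lines are higher after CHR. Right, the change in percentage points by mean level of the window (dots, lines; bars, mean ± SD of 4 lines); the windows of 80% and more are higher in 4 of 4 lines.

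Over all 4 lines, 10 windows passed the test for CHR against untreated, 3 higher and 7 lower; centring gave 12 and 35, logit levels 72 and 73, and windows of at least 1 kb 55 and 52. Among windows with a gene, the largest rise was inside GDA, which encodes the purine-degrading enzyme guanine deaminase (chromosome 9, 72149600 to 72150725). There the level rose by 56.4 ± 16.9 points (SD, n = 4, limma adjusted p = 0.00562). In burb1 it went from 24.5% to 97.3% and in fiaj1 from 10.3% to 43%. A window inside PKIB, which encodes an inhibitor of protein kinase A, rose by 41.1 ± 11.4 points (adjusted p = 0.0431). The largest fall at a window with a gene was at the high-coordinate end of the pseudogene MED15P5 (chromosome 2, 130252183 to 130253104), which fell by 65.6 ± 21.4 points (adjusted p = 0.00443). The long noncoding RNA gene LINC02625 fell by 50.4 ± 15.3 points at its high-coordinate end, from between 94.0% and 97.9% in the untreated lines, with H9 at 97.7%.

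Falls were also found 982 bp outside CTDP1-DT (-48.1 ± 21.9 points), 662 bp outside GRK4, a G protein-coupled receptor kinase gene (-43.6), inside SLC35F3, a solute carrier gene (-39.3 ± 13.2), and inside ZFHX3, a zinc finger homeobox transcription factor gene (-36.1 ± 10.5), with limma adjusted p between 0.0375 and 0.0482. Further windows went the same way in all 4 lines without passing. SPRY2, which encodes an inhibitor of receptor tyrosine kinase signalling, differed by 25.2 ± 10.0 points (adjusted p = 0.0563), RBPJ, the transcription factor of the Notch pathway, by 30.2 ± 13.4 (0.0657), and IRF2BP1 by 33.5 ± 4.38 (0.0572). CMKLR2-AS (33.7), DNASE2 (18.5), LOC105375482 (24.3), LOC107986638 (53.7) and LOC105375605 (19.6) were also above their untreated levels. A window in SOX2-OT, the noncoding RNA gene around the pluripotency gene SOX2, differed by -54.6 ± 29.8 points (0.0563), DLGAP2 by -43.1 (0.0504), CCNP by -39.7 (0.0548) and PNMA8B by -44.7 (0.0563).

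At an unadjusted p under 0.05, 4913 windows differed by at least 10 points. The 10 windows depended on the lines and on the model. Without burb1 1 window passed, without fiaj1 15, without sojd3 1 and without hehd1 488, and none passed when the limma prior had no trend. In simulated data for this fit 19 unchanged windows passed under 1 noise model and 0 under the other. The 19 passed beside 8, 39, 50 and 50 recovered changes of 10, 20, 30 and 50 points. False calls grow with the number of calls under this correction, so the 19 cannot be set against the 10 found. The 10 can still hold false calls.

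Because leaving out hehd1 moved the count that far, the fit on burb1, fiaj1 and sojd3 is described here. It is a choice made after the counts were seen, and the 3 lines were not named as a group by the labels. In these 3 lines 188 windows rose and 300 fell, and the 10 windows of the 4-line fit were among them. Centring each column gave 161 and 466, and logit levels 370 and 437. Falls outnumbered rises in each of these settings, and the size of the excess depended on the scale. Falling windows had a median length of 1390 bp and rising ones 2304.5 bp, against 4853 bp for all windows. A gene lay at or near 82% of the falling, 72.3% of the rising and 71.4% of all windows, differences that were not tested. The falling windows' median level went from 58.3% to 17.1% in burb1, from 73.6% to 24.2% in fiaj1 and from 77.9% to 20.1% in sojd3. In hehd1 the same windows had medians of 16.5% untreated and 19.5% after CHR, and in H9 28.7%. The rising windows had medians of 57.1%, 55.4% and 58.1% untreated and 87.9%, 88.6% and 90.3% after CHR in burb1, fiaj1 and sojd3. In hehd1 they had 80.5% and 80.2%, and in H9 82.8%. Untreated hehd1 was nearer to the CHR than to the untreated mean of the 3 lines at 274 of the 300 falling and 144 of the 188 rising windows. For H9 these counts were 239 and 141.

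The largest fall at a window with a gene was at ISLR2, which encodes a neuronal leucine-rich repeat protein. There the level fell by 83.9 ± 11.7 points (SD, n = 3 lines, chromosome 15, 74133523 to 74134115, limma adjusted p = 1.42e-05). It went from 94.1% to 2.44% in burb1 and from 91.3% to 1.85% in sojd3, while hehd1 had 2% untreated and 7.59% after CHR. NKX6-2, a homeobox transcription factor gene of the neural tube, fell by 73.5 ± 12.9 points and PRDM16, a zinc finger transcription factor gene, by 72.9 ± 10.7. MN1, a transcriptional coregulator gene, fell by 72.8 ± 10.7, SMARCA2, a chromatin remodelling ATPase gene, by 70.8 ± 24.4, and SOX2-OT by 69.0 ± 9.97. LOC105370824, LOC105377363, which overlaps PANCR, and LOC124903827, which overlaps PRDM16, fell by 77.4, 74.8 and 68.8. All of these windows had adjusted p of 0.000422 or less.

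The largest rise in the 3 lines at a window with a gene was 1023 bp outside the pseudogene FAM120A2P (73.5 ± 5.68 points, n = 3). Rises followed inside MARCKS, which encodes an actin-binding substrate of protein kinase C (59.7 ± 27.1), ZBTB22 (57.6 ± 4.80), EPS8L1 (57.6 ± 28.9) and IRS2, which encodes an insulin receptor substrate (56.9 ± 18.8). LOC107986638, ANKRD18CP, LOC124903908 and LOC112268032 rose by 68.3, 60.9, 58.3 and 56.8. Limma adjusted p lay between 3.22e-05 and 0.00422. MARCKS stood at 96.5% in untreated hehd1 and 71.3% after CHR, against 90.3% in H9.

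**Figure D2:**
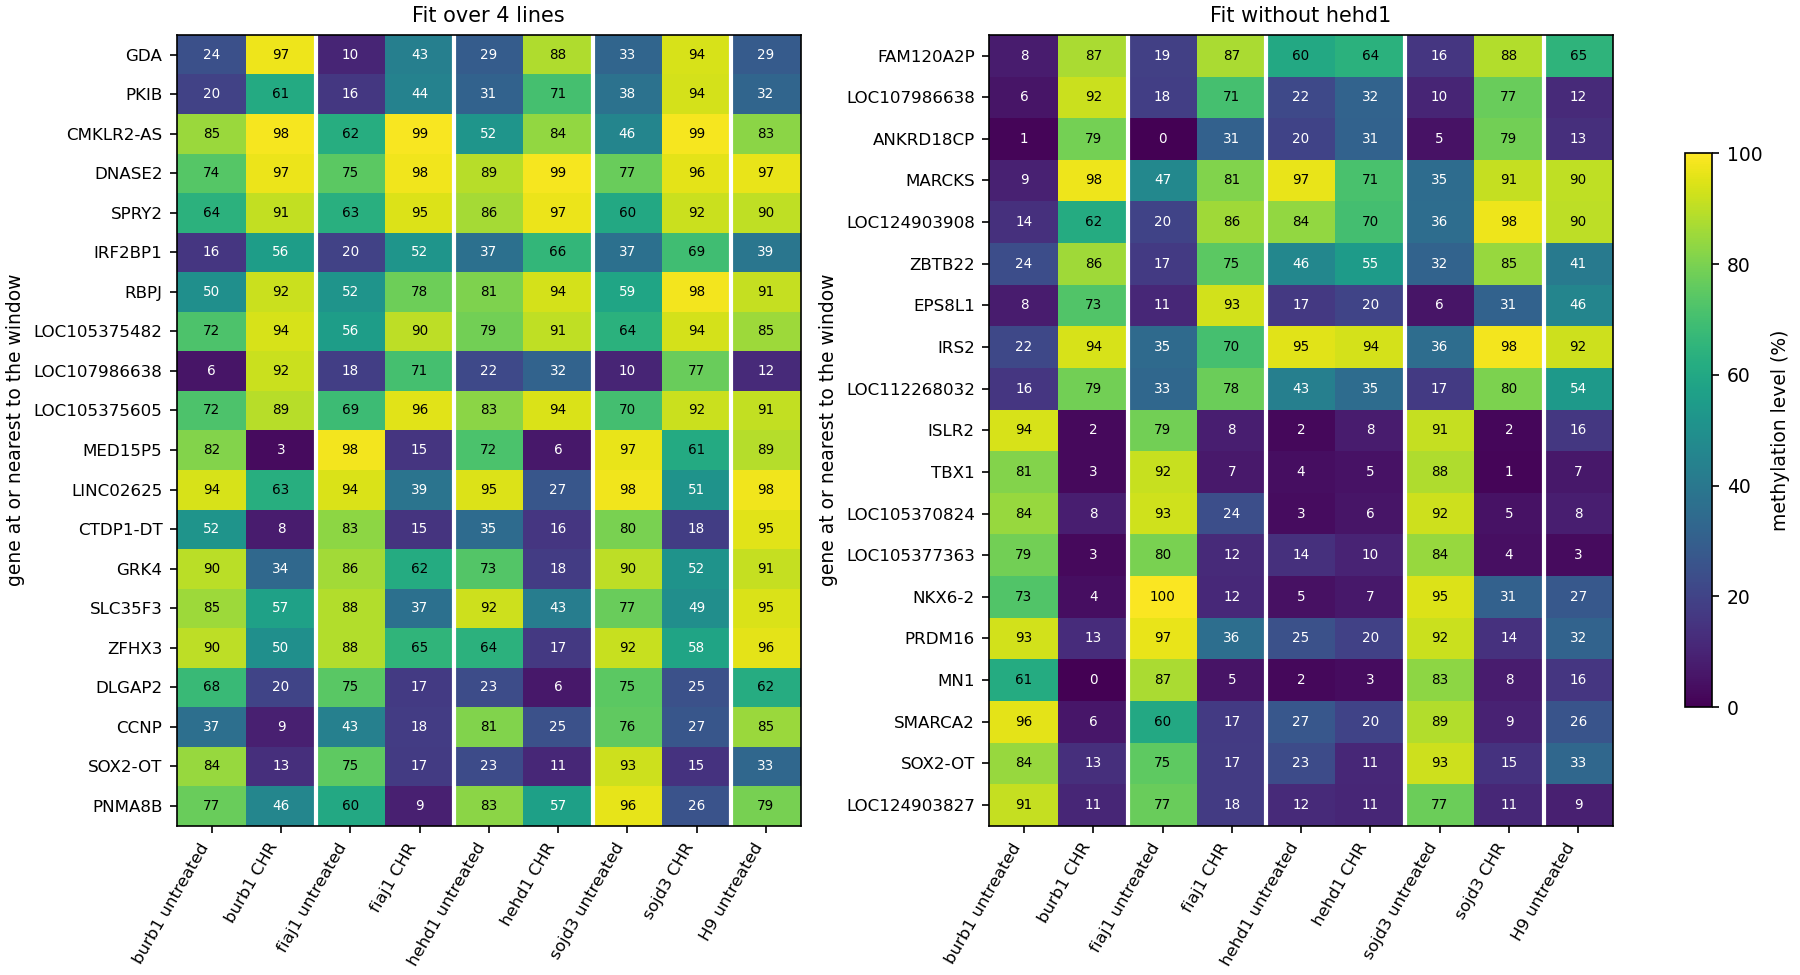
Methylation level in percent (colour and number) of each column at the windows named for the fit over 4 lines (left, including windows that did not pass) and for the fit without hehd1 (right), 1 window per gene. In the right panel untreated hehd1 and H9 are near the CHR columns of the other lines at ISLR2 and TBX1 (2% to 16.1%).

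TBX1 encodes a T-box transcription factor of pharyngeal and heart development. Of 14 windows in the gene (chromosome 22, 19756703 to 19783593, GRCh38), 8 passed in the fit without hehd1, all falls, between 19757111 and 19769504. At 19762943 to 19764158 the level fell by 83.5 ± 4.14 points (SD, n = 3 lines; limma adjusted p = 1.28e-05), from 81.5% to 2.58% in burb1, 91.8% to 6.91% in fiaj1 and 88.2% to 1.44% in sojd3. The hehd1 columns had 3.7% and 4.98% there, and H9 6.64%. At 3 of the 8 windows, from 19765367, 19766354 and 19767146, untreated burb1 had 11.8%, 9.01% and 8.84%, and the falls were mostly those of fiaj1 and sojd3. At the 6 other windows in the gene, toward its high-coordinate end, no difference passed, and from 19769505 to 19771421 the difference was -6.06 points (adjusted p = 0.394).

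**Figure D3:**
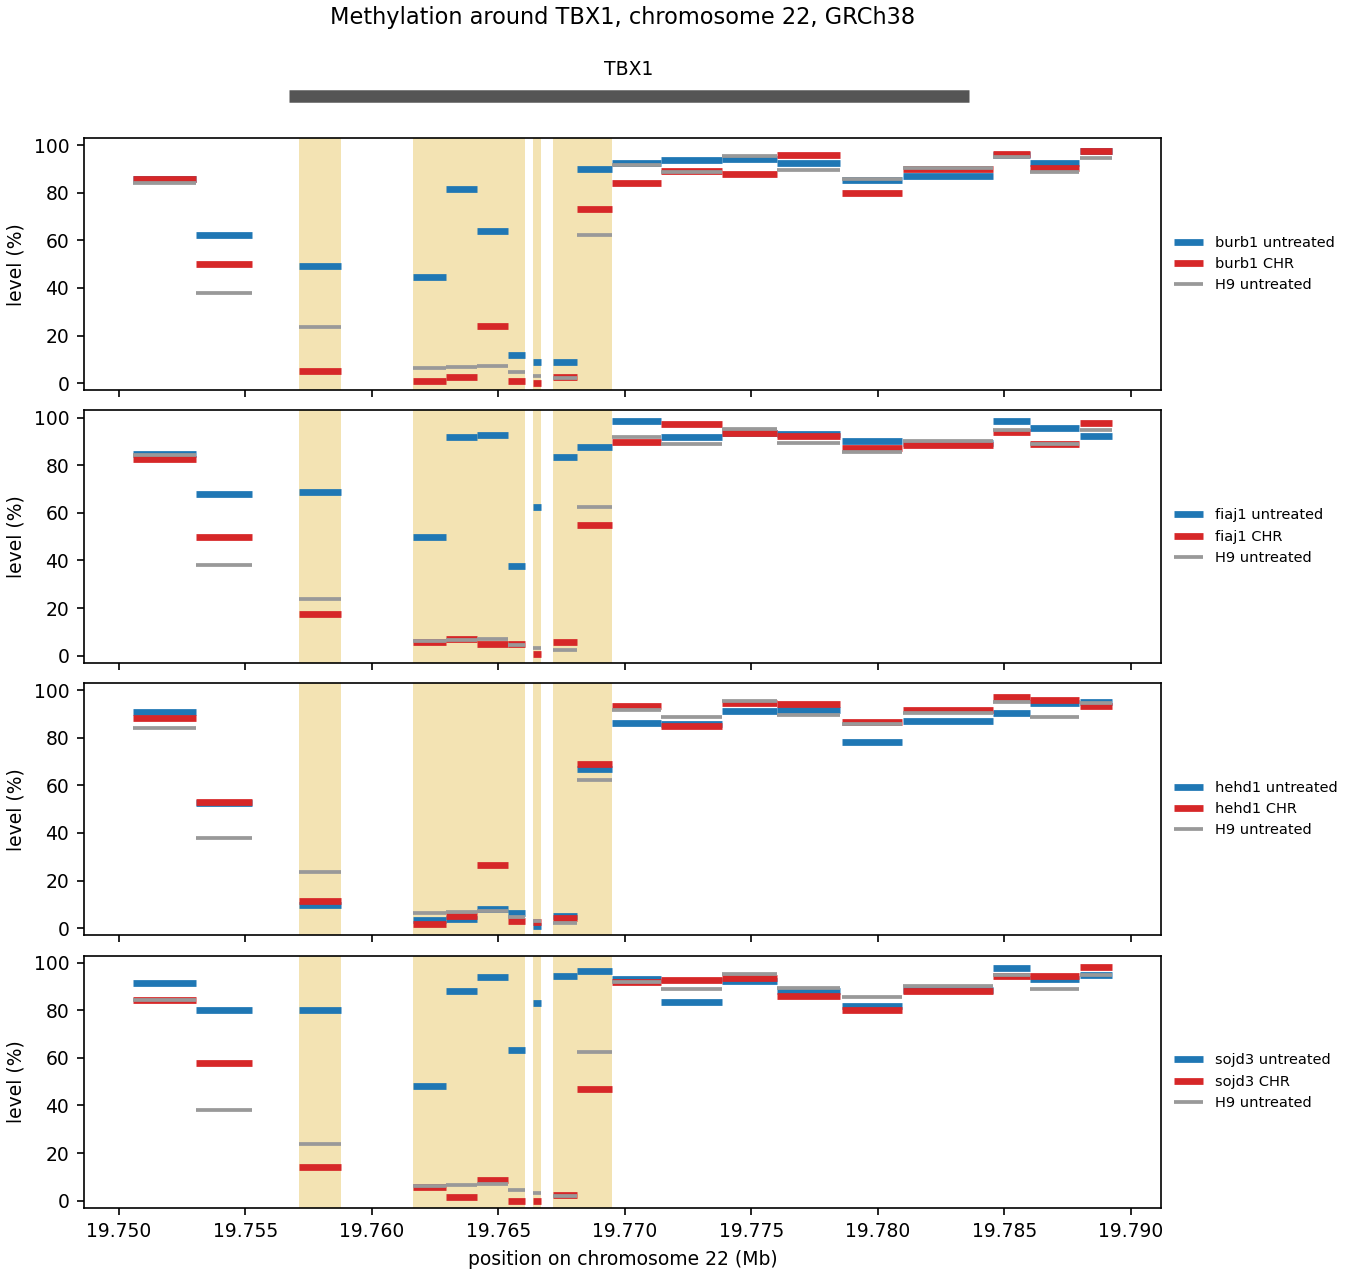
Methylation level in percent of each window along chromosome 22 around TBX1 (grey bar on top), 1 panel per line, with untreated (blue), CHR (red) and H9 (grey). Shaded windows passed in the fit without hehd1; in untreated burb1, fiaj1 and sojd3 the window at 19762943 is at 81.5%, 91.8% and 88.2%, and in hehd1 at 3.7%.

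The same procedure was then applied to each line in turn, with hehd1 among the reference lines of the others. For each line, 1000 windows were chosen in the other 3 lines, and the line was placed between their untreated level (0) and their CHR level (1). Untreated burb1 lay at 0.233, fiaj1 at 0.00971 and sojd3 at -0.0576. After CHR they lay at 0.900, 0.645 and 0.700. The differences were 0.666 (95% interval over chromosomes 0.564 to 0.769), 0.636 (0.533 to 0.738) and 0.758 (0.639 to 0.876). Untreated hehd1 lay at 0.902 and hehd1 after CHR at 0.885, a difference of -0.0174 (-0.0478 to 0.0130). H9 lay at 0.552, 0.418, 0.752 and 0.434 on the axes for burb1, fiaj1, hehd1 and sojd3. In the fits without burb1, fiaj1 and sojd3 only 1, 15 and 1 windows passed, against 488 without hehd1. Most of the 1000 windows on those axes thus did not pass. Windows picked in part by noise need not place an uninvolved column at 0, so these H9 positions do not show a place toward CHR. The intervals cover spread over chromosomes in these columns, not between cultures.

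**Figure D4:**
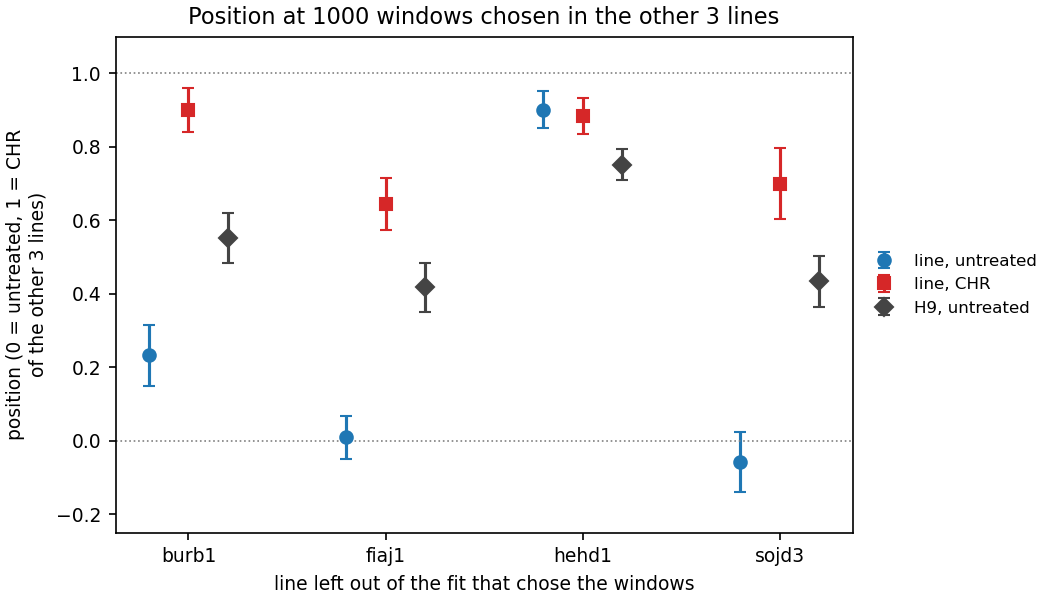
Position of each line at 1000 windows chosen without it, where 0 and 1 are the mean untreated and CHR levels of the other 3 lines; circles, untreated; squares, CHR; diamonds, H9; bars, 95% intervals over chromosomes. Untreated hehd1 is at 0.902, and the other untreated lines are between -0.0576 and 0.233.

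Whether the response to CHR differed between lines was tested as the change in 1 line against the changes in the other 3. The count of passing windows was 83 for burb1, 18 for fiaj1, 30 for hehd1 and 4 for sojd3. In burb1 CBLN4, which encodes a synaptic organiser of the cerebellin family, changed by -94.6 points against a mean of 3.30 in the other lines (limma adjusted p = 5.86e-05). ZNF667, a zinc finger gene, changed by -84.0 against 14.2, SULT1A1, a sulfotransferase gene, by -91.2 against 5.01, and LOC124903780 by 88.8 against 5.46. In hehd1 ISLR2 changed by 8.64 points against -83.3 (0.0106), PRDM16 by 18.5 against -68.9 (0.019) and TBX1 by 1.28 against -83.5 (0.013). Of the 1 window per gene shown for the fit without hehd1, which at ISLR2 and PRDM16 is another window, those at ISLR2, TBX1, LOC105370824 and MN1 passed this comparison (adjusted p 0.013 to 0.0475). The others did not, PRDM16 among them (0.167). The level at WDR74 went from 87.2% to 7.74% in hehd1, -79.5 points against 15.6 (0.000953), with SPRED3 at -66.8 against 43.2 and LINC00921 at -74.3 against 6.41.

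In fiaj1 the largest differences among windows with a gene were at MYH7B (39.7 points against -49.7), ZNF648 (73.9 against -1.12), RCN1P1 (52.7 against -21.4), HNRNPD (-57.9 against 1.85), DAG1 (-47.6 against 3.78) and TNFAIP2 (-49.6 against -0.517). In sojd3 they were at ALG12 (49.3 against -0.13), LOC112268425 (-79.9 against -8.99) and CYP26C1, a retinoic acid hydroxylase gene (-54.6 against 1.08). The burb1 windows were 10 with a higher and 73 with a lower change than the other lines, and the hehd1 windows 17 and 13. For sojd3 the split was 1 and 3, against 3 and 16 after centring. These counts rest on a prior that follows the mean level, set after a prior that followed the mean change had passed 0 windows in every line; without a trend they were 6, 0, 18 and 0 for burb1, fiaj1, hehd1 and sojd3. Each compares 1 value with a spread taken from the other 3 lines. In simulated data unchanged windows passed under 1 noise model, beside recovered changes, and none passed under the other. False calls grow with the number of calls, so the simulated number cannot be set against the count of a line. The counts can still hold false calls.

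Within a line, 1 value per condition allows no test, and changes are counted by size. At least 10 points higher or lower were 20999 and 8997 windows in burb1, 35233 and 12298 in fiaj1, 16789 and 10167 in hehd1, and 17935 and 12350 in sojd3. With each column centred on its median, which was higher after CHR by between 1.13 and 2.29 points, the counts were 12273 and 14120, 18201 and 21551, 11671 and 14180, and 10928 and 17848. As a background, pairs of untreated lines differed by 10 points or more at between 29563 and 45865 windows. The largest changes in burb1 among windows with a gene were at SALL3, a spalt-family transcription factor gene (100% to 3.03%), CBLN4 (96.5% to 1.81%), SCARF2 (97.2% to 3.59%), LOC124903780 (9.88% to 98.6%), MARCKS (9.09% to 97.6%) and LOC107986638 (5.77% to 91.9%). In fiaj1 they were at EPS8L1 (11.2% to 93.1%), UCKL1 (19.6% to 94.7%), ZNF568 (24.6% to 98.6%), SCGB3A1 (96.2% to 4.81%), TBX1 (92.9% to 4.76%) and NKX6-2 (99.5% to 11.6%).

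In hehd1 the largest changes among windows with a gene were at LOC124906269 (32.9% to 95.5%), HSPH1, a heat shock protein gene (0% to 61.3%), GDA (29.0% to 88.0%), DSCR9 (94.3% to 4.59%), WDR74 (87.2% to 7.74%) and POTEE (87.6% to 11.3%). In sojd3 they were at ZNF649 (16.5% to 90.4%), ANKRD18CP (4.99% to 78.6%), FAM120A2P (15.8% to 88.3%), TBX1 (94.4% to 2.54%), LOC105371225 (95.7% to 4.17%) and ISLR2 (96.8% to 6.02%). Many of these windows are shorter than 1 kb, and the counting error of each value is unknown.

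H9 was set against the untreated lines, and 115 windows passed, 97 higher in H9 and 18 lower; centring gave 85 and 39. At the high-coordinate end of CSRP1, a LIM-domain protein gene (chromosome 1, 201506891 to 201507348), H9 had 99.7% against 1.21% to 30.1% in the 4 lines, a difference of 89.7 points (SE 8.90; limma adjusted p = 0.00131). DDX41, an RNA helicase gene, had 89.4% in H9 and at most 8.79% in the lines (adjusted p = 3.18e-05). KLB, which encodes the FGF co-receptor beta-klotho, differed by 86.1 points, TMEM151B by 81.9 and CYTH2 by 74.0. H9 was lower at CBLN4 (20.5%, a difference of -74.8 points), SIM1, a transcription factor gene of the hypothalamus (48.8%, -43.0), LOC100128885 (-41.9), LOC124904707 (-40.8) and BOK, a BCL2-family gene (-39.2). Each difference rests on 1 H9 column, whose spread is assumed to be that of the other lines, and both H9 libraries are from batch 1. H9 is also a single embryonic line against induced lines, so line, origin and batch cannot be told apart. Logit levels gave 41 higher and 1 lower, and 64 passed without burb1.

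Against the CHR columns 192 windows passed, 146 higher in H9 and 46 lower. CSRP1 and DDX41 were again among the largest, at 88.2 and 85.7 points. CR1L, a complement receptor-like gene, had 96.0% in H9 and 3.96% or less in the lines after CHR (limma adjusted p = 1.07e-05). ANK1, the erythroid ankyrin gene, had 94.1% in H9 and 8.33% or less after CHR, where untreated fiaj1 and sojd3 had 72.1% and 87.8%. A window inside PCDHGA1, which also overlaps the other gamma protocadherin genes, had 93.3% in H9 and 15.6% or less after CHR, with 90% in untreated sojd3. Lower in H9 were SMIM3 (29.9%, -54.6 points), SIM1 (42.6%, -53.9), CMKLR2-AS (-40.4), BOK (-39.0) and MYO1C (-35.7). Logit levels gave 37 higher and 1 lower, and the count was 117 without burb1, 127 without fiaj1 and 108 without hehd1.

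Whether CHR moved the lines toward H9 over the whole genome was asked by correlating, across windows, the change with CHR and the difference of H9 from the untreated lines. With different lines in the 2 quantities, Pearson's r was 0.0780, and 2 of the 16 exchanges of CHR and untreated within lines gave an r as large, the real one included (one-sided exact permutation p = 0.125). Windows are not independent replicates. When the same untreated lines entered both quantities, r was 0.360 against 0.316 simulated without any effect, and the covariance was 5.58 against 3.18. Leaving out a line gave r of 0.0389 without burb1, 0.0252 without fiaj1, 0.133 without hehd1 and 0.0236 without sojd3. The mean absolute difference from H9 went from 4.34 to 4.08 points in burb1, from 4.95 to 4.29 in fiaj1, from 4.30 to 4.24 in sojd3 and from 4.27 to 4.29 in hehd1. These distances include the shift in mean level. Column means were 85.3% to 86.3% untreated and 87.0% to 87.5% after CHR, with H9 at 86.9%. No centred form or test of the distances is given, so they do not show a move toward H9 apart from that shift.

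Gene ends were compared by the 16 gene lists. No gene end passed over 4 lines in limma, with 486 at an unadjusted p under 0.05 and 10 points or more, so the members named here are given by value. The median of a column over gene ends was higher after CHR by 1.20 points on average, and list medians are given before this shift is taken off. Taken off, the medians of the Wnt, protocadherin, imprinted, primed and formative, variably methylated, chromatin regulator, trophoblast and fibroblast lists turn negative, between -0.0344 and -1.17, and no other median changes sign. Core pluripotency genes had a median change of 2.36 points (15 of 20 higher; camera adjusted p = 0.139). NANOG, a homeobox gene of pluripotent cells, differed by 17.0 ± 7.87 points (SD, n = 4), with untreated levels of 9.01% to 19.01% and CHR levels of 25.2% to 35.4% (limma adjusted p = 0.48). It was the 1 member that passed when adjusted over the list alone. TERT differed by 8.47 and GDF3 by 5.98. POU5F1, which encodes OCT4, differed by 6.66 ± 8.74, SOX2 by -1.67 ± 4.80 and DNMT3B, a DNA methyltransferase gene, by 3.57 ± 1.87.

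Lists of developmental genes had negative medians. Anterior neural fate genes changed by a median of -0.781 points (19 of 31 lower) and had a camera adjusted p of 0.00352, with SIX3 at -14.4 ± 15.2, FEZF1 at -6.80 ± 5.73 and SP8 at -5.97 ± 4.08, all forebrain transcription factor genes. Primitive streak, mesoderm and endoderm genes had a median of -0.604 (18 of 31 lower; camera adjusted p = 0.0169), with CDX1 at -18.6, FGF17 at -18.2 ± 17.6 and GATA4 at -15.9 ± 11.2. Neural crest and later neural markers had a median of -0.808 (17 of 29 lower; camera adjusted p = 0.0169), with SOX9 at -5.31 and ELAVL4 at 8.72. With an estimated correlation all 3 had an adjusted p = 0.406, and fry, which tests whether a list moved on balance 1 way and does not compare it with other gene ends, gave adjusted p of 0.369, 0.336 and 0.336. None of their members passed over all genes or adjusted over the list alone. The gene ends of these lists had median untreated levels of 6.18%, 28.6% and 11.2%, while camera compares them with all gene ends, and the higher mean level after CHR lay in windows of 80% and more. Without sojd3 no list passed, and without burb1 only anterior neural fate did. Without fiaj1 the primitive streak, mesoderm and endoderm list did not pass (adjusted p = 0.0524) and imprinted genes did (0.0473).

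**Figure D5:**
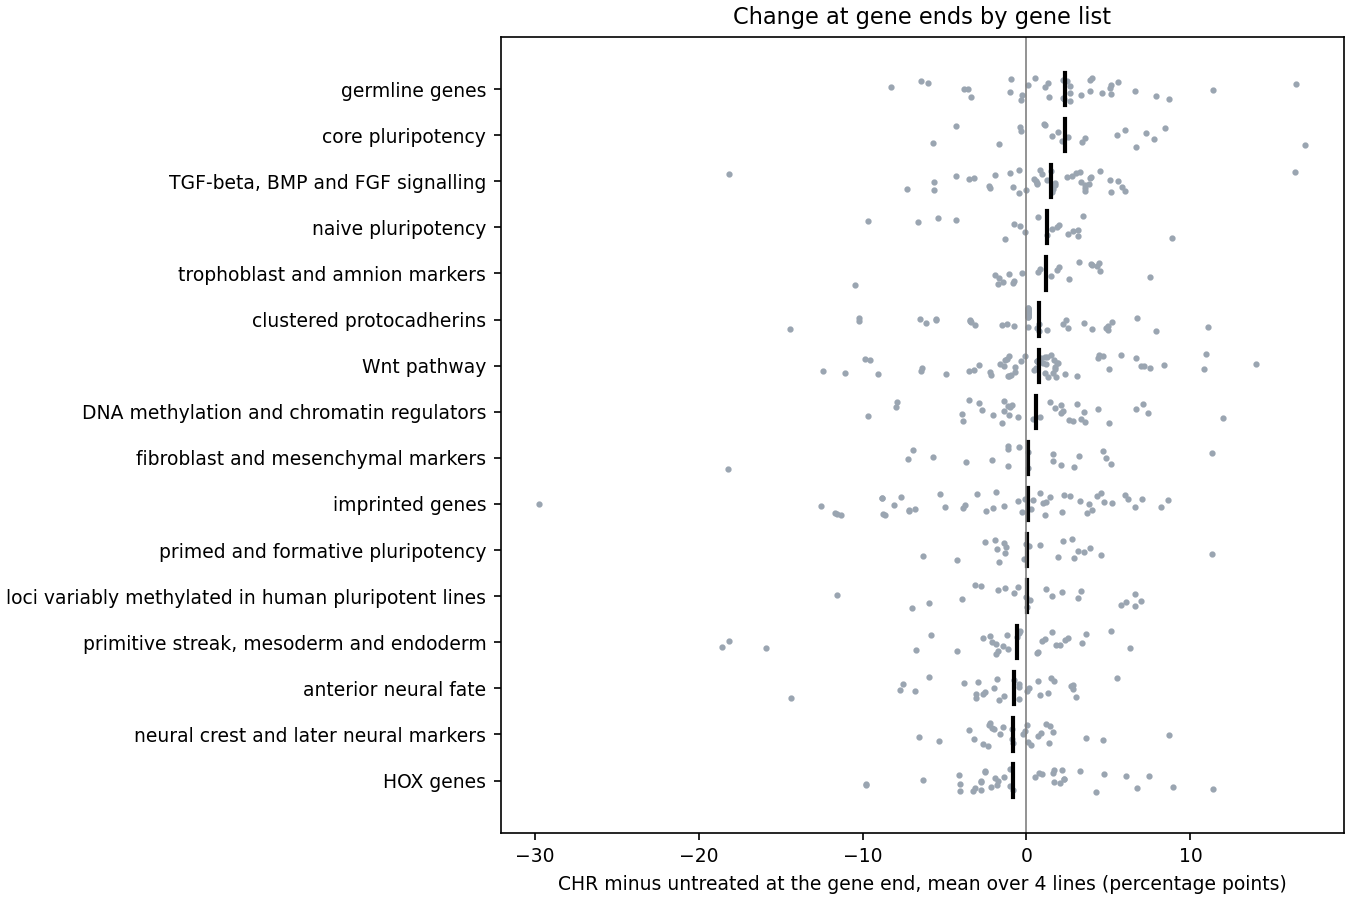
Change with CHR at gene ends in percentage points, mean over 4 lines, for the members of each list (dots) and their median (bar). Medians lie between -0.83 for HOX genes and 2.37 for germline genes, and no single gene end passed the test over all genes.

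The other lists did not pass camera. HOX genes had a median of -0.83 and a mean of 0.343 points, and camera ranked them below other genes (18 of 35 units lower; adjusted p = 0.181), with HOXB2 and HOXB3, which share their windows, at -9.81 and HOXC10 at 7.45. Wnt pathway genes had a median of 0.735 (36 of 61 higher; 0.282) although camera ranked them below other genes, with the secreted Wnt antagonists SFRP4 at -9.84 and SFRP1 at -9.53 and the Wnt effector LEF1 at 8.38. TGF-beta, BMP and FGF signalling genes had a median of 1.49 (30 of 45 higher; 0.68), with FGFR2 at 16.4. Germline genes had a median of 2.37 (26 of 36 higher; 0.3), with DPEP3 at 16.4 ± 4.21, the 1 member that passed adjusted over the list alone, SYCP1 at 8.68 and SOHLH2 at 5.07. Imprinted genes had a median of 0.0881 and a mean of -1.51, with camera below other genes (24 of 48 units higher; 0.094), with MKRN3 at 6.62, SVOPL at 6.02 and CDKN1C at -8.75.

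Clustered protocadherins had a median of 0.753 (18 of 29 units higher; camera adjusted p = 0.64). PCDHA6 at -14.4 ± 8.17 and PCDHA11 at 11.1 ± 3.67 passed adjusted over the list alone, in opposite directions, and PCDHA2 stood at 7.91. Naive pluripotency genes had a median of 1.28 and a mean of 0.144 (11 of 19 higher; 0.68), with ZFP57, a factor that keeps imprints, at -9.66, DPPA3 at 8.88 and DPPA5 at 3.13. Primed and formative genes had a median of 0.0506 (11 of 22 higher; 0.64), with THY1 at 11.3, DUSP6 at -6.29 and FST at 3.86. Regulators of DNA methylation and chromatin had a median of 0.6 (19 of 36 higher; 0.68), with UHRF2 at 11.99 and MBD4 at 7.39. Camera placed these 4 lists below other genes although their medians were positive. Loci variably methylated in human pluripotent lines had a median of 0.03 (12 of 23 higher; 0.64), with BRDT at 6.61, DPP6 at 6.64 and MEG3 at -11.6. Camera ranked this list and that of fibroblast and mesenchymal markers below other genes, and the mean of the fibroblast list was -0.479. Markers of other cell types did not pass either. Trophoblast and amnion markers had a median of 1.17 (13 of 22 higher; 0.919), with KRT18 at 7.52, ERVFRD-1 at 4.31 and TP63 at 3.99. Fibroblast and mesenchymal markers had a median of 0.103 (11 of 21 higher; 0.3), with COL1A1 at -18.2 ± 16.4 and FBN1 at -7.24.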

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

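The tests of incomplete conversion, of coverage and of exchanged columns, and the comparison of 1 line with the other 3, were chosen after the result was seen; the comparison at windows where H9 lies at the untreated level and the exchanges within lines were set down before their results.

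In groups of 4 lines, 1 column stood far from the other 3 in 10 of 80 groups examined. Chance would give about 4 in independent groups not chosen from these data. The groups include windows picked from these same columns, so the 4 cannot be set against the 10. The difference between the CHR and untreated positions of hehd1 was -0.0174 on the axis of the other lines, where the 3 other lines had 0.636 to 0.758. Untreated hehd1 stood apart at SPRY2 (86.4% against 60.3% to 64.3%), ZFHX3 (64.4% against 88.4% to 91.7%), DLGAP2 (23.2% against 67.8% to 75.0%) and CR1L (60.8% against 0% to 2.39%). After CHR, hehd1 stood apart at CMKLR2-AS (83.9% against 98.5% to 99.0%), fiaj1 at GDA (43% against 88.0% to 97.3%), burb1 at CBLN4 (1.81% against 97.0% to 100%) and sojd3 at PCDHGA1 (15.6% against 0% to 2.38%). Untreated sojd3 stood apart at LINC02625 (97.9% against 94.0% to 94.6%). The change of 1 line against that of the other 3, which supply the spread, passed a test of the difference at 83 windows in burb1, 18 in fiaj1, 30 in hehd1 and 4 in sojd3, and at none with the prior used first. In simulated data unchanged windows also passed this comparison under 1 noise model, beside changed windows that were recovered. Their number cannot be set against the counts of a line, which can hold false calls. In hehd1 the level changed by -25.2 points at MARCKS and by -13.9 at LOC124903908, where the 3 other lines rose; in the same comparison these 2 differences, -84.8 and -72.2 points, did not pass (limma adjusted p = 0.167 and 0.103).

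The mean level was higher after CHR in all 4 lines. Incomplete enzymatic conversion of the CHR libraries would raise windows of low level most. Windows averaging under 5% changed by -0.0721 points (SE 0.176, 4 lines) against 1.38 over all windows, and mitochondrial windows by -0.599. These values argue against incomplete conversion as the whole source. They bear only on unmodified cytosines read as methylated. The opposite error, methylated cytosines read as unmodified in the untreated libraries, was not tested. A filter or coverage that differed between columns stays open: in the 1 line with values in more windows after CHR, fiaj1, the rise was 1.94 points, against a mean of 1.19 in the others, and 1 line decides nothing. The change of medium and coating and the passages that came with the treatment are confounded with it and were not tested.

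Untreated hehd1 lay near the CHR columns on the axis of change of the other 3 lines. An exchange of the 2 hehd1 columns could give this position only if the CHR column lay near 0, and it lay at 0.885 (0.836 to 0.934). That argues against an exchange as the source of the position. Because both columns lay near 1, their positions cannot show whether the columns were exchanged. Exchanging them raised the passing windows of the 4-line fit from 10 to 112. To ask whether untreated cells had received CHR, 118 windows were taken where H9 lies at the untreated level of the other lines. There untreated hehd1 lay at 0.612 and hehd1 after CHR at 0.909, a difference of 0.297 (0.167 to 0.428 over chromosomes). A full treatment would give equal positions only if treated cultures did not differ, which the interval does not cover. At windows taken in the same way for the other lines, the CHR columns lay at 0.873 in burb1, 0.517 in fiaj1 and 0.534 in sojd3. Full treatment of the untreated hehd1 column is therefore not excluded. At the 567 windows where H9 lies at the CHR level, untreated hehd1 lay past hehd1 after CHR (1.01 against 0.926, difference -0.0835, -0.106 to -0.0608). Treatment of part of the cells would put the column between the line's own untreated level and its CHR level. That untreated level is not known, so this position does not decide. The bound set beforehand against such treatment, untreated under 0.5 of the CHR position at the 118 windows, was not reached. The intervals do not cover differences between cultures, so full or partial treatment cannot be told apart from a state of the line. That untreated hehd1 may already be in the state the other lines reach with CHR is a hypothesis, and neither competence nor culture history of the lines was given to test it.

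Differences between lines were smaller after CHR, at a mean of 4.10 points between pairs against 4.33 in untreated cells. The fall was -0.0852 without fiaj1 and -0.371 without sojd3, and 3 of 6 pairs differed by 30 points at more windows after CHR, such as burb1 and sojd3 at 1153 against 739. The 16 exchanges of CHR and untreated within lines are too few for a share under 0.05. Of them, 6 gave a fall as large as the real -0.233, and the lowest of the others was -0.402. The differences were taken on levels that include each column's mean. Those means spread less after CHR (SD 0.234 against 0.432 untreated, n = 4 lines), which can shrink the differences by itself. No centred value is given, so the fall does not show that single windows became more alike.

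Exchanging CHR and untreated within lines is too coarse to give a share under 0.05 for the fits over all windows. With 4 lines, 2 of 8 exchanges passed as many windows as the real 10, and the highest other, with only the hehd1 columns exchanged, passed 112, which points to a structure of the columns whose cause this count does not show. Without hehd1, 1 of 4 exchanges, the real one, passed 488, and the highest other passed 0. At gene ends 8 of 8 exchanges, the real one included, passed 0 in limma, with 486 in the real one at an unadjusted p under 0.05. For gene lists 1 of 8 exchanges, the real one, passed 3, and the highest other passed 2.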

How the results depend on the processing

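No paired analysis was possible because the columns carry no replicate numbers, where this means pairs of replicates; the 2 columns of a line were paired. Filters on coverage could not be run without read counts, nor batch terms and exclusion of replicates or of libraries with control DNA on columns that combine libraries. Chosen after the data were seen were the settings without a line block, the priors, the limits of at least 3 lines and at least 1 kb, all alternatives to the fits with 1 line left out, lines left out for H9 and gene lists, gene ends averaged, the 200 and 5000 windows of the axis, all windows of a column, and the exchange of all 8 columns. Except where stated, the cause of a change was not tested.

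The 10 windows over 4 lines became 145 on logit levels (72 higher, 73 lower) and 47 after centring (12 higher, 35 lower), and all 10 were among both. They became 107 with windows of at least 1 kb (55 and 52), 1 without a line block, 1 with values in at least 3 lines and 0 with a prior without trend; 20 points left 10, and chromosomes 8, 19 and 20 left out gave 8, 12 and 11. Leaving out 1 line gave 1 to 488. The single window without burb1 became 34 on logit levels, 11 after centring and 0 without trend, the 15 without fiaj1 43 on logit levels and 2 without trend, and the single window without sojd3 13 on logit levels and 6 after centring. The 488 without hehd1 became 807 on logit levels (370 higher, 437 lower), 627 after centring, 439 without trend and 453 at 20 points. Of the 20 named over 4 lines, 12 passed newly on logit levels and 10 after centring; leaving out 1 line ended the call of a named window 17 times, for GDA among them without burb1 (adjusted p = 0.0798) and without sojd3 (0.151), and gave 12 new ones. The 20 taken by the same kind of rule without hehd1 passed under both.

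Within lines, 20 points in place of 10 left 3583 windows in burb1, 5295 in fiaj1, 2636 in hehd1 and 4099 in sojd3, since fewer windows can pass a higher limit. In the comparison of 1 line with the other 3, the 135 windows became 51 on logit levels, 183 after centring, 24 with a prior without trend and 0 with a prior that follows the mean change. That last prior was the one first run, and it was replaced after its count of 0 had been seen, so the 135 windows depend on a choice made with the outcome known. H9 against the untreated lines gave 42 on logit levels (41 higher, 1 lower) and 64 to 165 with 1 line left out (64 without burb1, 165 without hehd1), and against the CHR lines 38 (37 and 1) and 108 to 138.

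The change in the mean level kept its sign, at 1.19 to 1.53 points with 1 line left out, 1.69 for medians and 1.52 over all windows of each column. Exchanging all 8 columns without regard to the line gave p = 0.0286 for the same 1.38 points in an exact permutation test, because that scheme allows a smaller p. The correlation with H9 stayed positive, at 0.0459 by rank. With 5000 windows the difference on the axis was 0.535 for burb1 and 0.607 for sojd3, and that of hehd1 was -0.00134. The 3 gene lists became 0 with an estimated correlation, 10 over gene spans, 6 with both gene ends averaged, and 0 to 3 with 1 line left out (1 without burb1, 0 without sojd3, and 3 without fiaj1, where imprinted genes took the place of the primitive streak, mesoderm and endoderm list). With fry, which asks whether a list moved on balance 1 way and not whether it differs from other gene ends, 0 lists passed. Depth is unknown, so no setting shows what more reads would change.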

Other observations

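The windows, gene ends and overlaps given here were chosen after the fit without hehd1 had been seen, while the gene lists had been fixed before.

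Members of the gene lists were counted at windows that fell in burb1, fiaj1 and sojd3, and no list passed the correction. Of the neural crest and later neural markers, 4 were at falling windows, where random windows of the same length and level held 0.78 on average (permutation p = 0.01 from 1000 draws, adjusted p = 0.16 over 16 lists). GBX2, a transcription factor gene of the hindbrain side of the midbrain boundary, differed by -53.9 points (limma adjusted p = 0.00291), with 19.4% in untreated hehd1 and 23.7% in H9. EN2, of the midbrain and hindbrain, differed by -37.8, OLIG2, of the ventral neural tube, by -26.1 and LMX1B by between -24.6 and -39.8 at 4 windows. Of the primitive streak, mesoderm and endoderm list, 3 members were at falling windows against 0.843 at random (permutation p = 0.045, adjusted p = 0.36). They were CDX1, a caudal-type homeobox gene (-58.3 points), FGF17 (-55.0) and GATA4 (-42.4). Each other list held 0 or 1 member at falling windows, with no permutation p under 0.29: anterior neural fate 1 (FEZF1, -28.7 points) against 0.875 at random, the Wnt pathway 1 (WNT7B, -27.8) against 1.12 and HOX genes 0 against 1.39. Among the rising windows were the Wnt receptor gene FZD5 (36.6), SPRY2 (30.0), SOX9 (27.9) and HOXA7 (27.7), each the 1 member of its list there, with permutation p between 0.19 and 0.39.

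At gene ends 5 genes passed in the fit without hehd1, out of 17723 units, and 805 at an unadjusted p under 0.05. INPP5A, an inositol phosphatase gene that shares windows with NKX6-2, fell by 57.9 points (SE 3.68; limma adjusted p = 0.0179), BHLHE23, a neural transcription factor gene, by 46.4 and SFTPC, a lung surfactant gene, by 34.2. IFITM1, an interferon-induced gene, rose by 45.0 and HPDL by 41.1. HPDL stood at 92.2% in untreated hehd1 and 83.6% in H9, against 7.47% to 19.2% in the other untreated lines.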
